A study of Mus musculus with 9 samples.

How the data were processed

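RNA was measured in basal cells of the mouse sebaceous gland, the lipid-secreting gland attached to the hair follicle. Per the labels' protocols, the cells were cut by laser capture microdissection from fresh frozen tissue of C57BL/6 mice that carried an inducible Cre at Lrig1 and a multicolour reporter at Rosa26. Libraries were made with a stranded kit for low input amounts, which copies total RNA and not only polyadenylated RNA. The 9 libraries fall into 3 ages by their labels, postnatal days 4, 10 and 30 (P4, P10 and P30), with 3 libraries at each age. The titles number the libraries 2, 3 and 4 at P4, and 1, 2 and 3 at P10 and P30. The labels do not say how many animals or captured regions stand behind a library, so p-values measure only the spread between these samples, which may be technical. Several regions or libraries of 1 animal would make the p-values too small.

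The deposited values are raw read counts per gene symbol, per the file headers, with 24972 symbols in each library. The submitters' processing notes name Trimmomatic 0.32 for trimming, STAR for alignment, featureCounts 1.5.1 for counting and the mm10 genome build. The version of STAR, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Reads from overlapping or antisense genes, and from close paralogs, are therefore uncertain in their assignment. Genes encoded by the mitochondrial genome were not analysed here. Coordinates are those of the RefSeq annotation of GRCm38, the assembly that mm10 names. In that annotation 24407 of the 24972 symbols were matched.

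Counts were analysed with R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16, which left 14670 genes. Library sizes were scaled by the trimmed mean of M values (TMM). With library totals alone the median log2 fold change of all genes was 0.13 for P10 versus P4 and -0.16 for P30 versus P10, against 0.05 and -0.02 with TMM, and the medians of the gene lists called below kept their sign under each scaling tried. The main test was edgeR's quasi-likelihood test fitted on all 9 libraries without covariates, with Benjamini-Hochberg adjustment over the 14670 genes and a threshold of 0.05. A test with 2 degrees of freedom asked whether a gene differed among the 3 ages, and 3 contrasts compared the ages in pairs. Expression is given as CPM, the count scaled to a common library size with TMM factors, as mean ± SD over 3 libraries. Log2 fold changes are given ± an approximate SE, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. For genes near 0 counts this SE cannot be relied on. The common dispersion was 0.511, a coefficient of variation of 71.5% between libraries of 1 age. Where all libraries of an age had 0 counts, a fold is a lower bound against a floor of 3 counts over the group, which covers counting error only, since reads amplified by PCR are not independent molecules.

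Before the data were examined, 35 gene lists with 557 genes were fixed, covering sebaceous and epidermal cell states, metabolic, growth and signalling pathways, and markers of 13 other cell types that a captured region could hold. Of these, 33 had at least 5 tested members. Each was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes, with adjustment over the 33 lists. The mitochondrial-encoded list, with 0 measured members, and the erythroid list, with 2, were not tested. An estimated correlation and the fry test were run beside it. For each list, members past the threshold were counted over all genes and adjusted over the list alone. The adjustment over a list alone does not cover the other lists or the other comparisons. Member calls that rest on it are therefore weaker than calls over all genes.

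The rule for the named genes was also fixed in advance. It took up to 7 genes with the largest rise and 7 with the largest fall in each pair of ages, among genes past the threshold with a mean of at least 10 CPM at the higher age and ranges that did not overlap. Ranges of 3 libraries against 3 fail to overlap by chance in 10% of genes. It also took up to 2 members per direction of each list described and, where no member passed the threshold, the 2 members with the smallest p, given as values. The last part of the rule was a fixed set of genes, among them Lrig1, Krt5, Krt14, Pparg, Scd1, Mki67, Prdm1 and Gata6. Some results that the rule asks for are not reported here. Other named genes were chosen after their values were seen, and the text says so.

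The steps were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed at P30 and 14214 genes past the filter. For P30 versus P4 the edgeR test recovered 0 of 49 genes changed 2-fold, 11 of 49 changed 4-fold, 27 of 47 changed 8-fold and 20 of 48 changed 16-fold, with 3 false calls and 0 calls in the wrong direction. For P30 versus P10 it recovered 0 of 49, 12 of 49, 26 of 47 and 24 of 48 genes at those sizes. In the simulated P10 versus P4 contrast, where no gene was changed among the 14214 genes, 0 were called. Each simulated gene had the same dispersion in all libraries. In the real data limma's sample quality weights ran from 0.246 in P4 library 3 to 3.01 in P30 library 1. The recovered and false calls may therefore differ in libraries of such unequal quality. Camera called the simulated changed list and 0 of 50 random lists for P30 versus P4. The simulated genes were drawn independently of each other, so this does not test camera on lists whose members vary together. In the real data the estimated correlation for P30 versus P4 was 0.79 in the hair shaft list and 0.877 in the skeletal muscle list.

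The alternatives fixed in advance were other scaling factors, other filters, DESeq2 1.42.0, limma-voom with and without sample quality weights, a fit of only the ages compared, the replicate number as a block, a test against a fold of 1.5, and leaving out each library in turn. After the data were seen, 5 more were added: leaving out the 3 libraries with the fewest detected genes, leaving out Rn45s with the muscle and hair genes, a skeletal muscle covariate, robust estimation, and a fit of the 4 libraries numbered S2 to S5. The first of these leaves P4 library 2 alone at P4. The muscle gene Ttn, part of the covariate, had 38200 to 55200 CPM at P30, at most 27000 at P4 and at most 18600 at P10. The covariate is therefore confounded with age at P30, and fits with it cannot separate age from muscle RNA.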

Results

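Gene expression was compared in basal cells captured from mouse sebaceous glands at P4, P10 and P30, with 3 libraries at each age. The series was designed to compare gland progenitors during morphogenesis with those at steady-state homeostasis. The labels state that hair follicles were in anagen, the growth phase, at P30. Each library held between 10018141 and 20595681 counts. Genes with at least 1 count numbered 15719, 12165 and 13063 in P4 libraries 2, 3 and 4. They numbered 19203, 17194 and 15162 in P10 libraries 1, 2 and 3, and 17200, 17292 and 13750 in P30 libraries 1, 2 and 3. Spearman correlations of log2 CPM were 0.815 to 0.953 between libraries of 1 age and 0.792 to 0.955 between libraries of different ages.

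Transcripts of basal keratinocytes were present at all ages. Krt5, a basal keratin, had 1609 ± 117 CPM at P4, 2010 ± 353 at P10 and 1208 ± 239 at P30 (SD, n = 3). Lrig1, the marker of the upper follicle stem cells whose promoter drives the Cre in these mice, had 147 ± 15.6, 153 ± 48.0 and 79.6 ± 8.48 CPM. The sebocyte regulator Pparg had 89.3 ± 62.2, 18.6 ± 6.20 and 36.3 ± 31.6 CPM, and the desaturase Scd1 4729 ± 3399, 1562 ± 651 and 4916 ± 4782 CPM. None of these 4 genes passed the edgeR test over all genes in any pair of ages. Nor did Krt14, Mki67, Prdm1 or Gata6, also named in advance, whose smallest edgeR adjusted p was 0.551, of Prdm1 in P30 versus P4.

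Marker transcripts of other tissue were present beside those of the gland. The hair shaft and inner root sheath list took 2.91 to 19.1% of a library's counts, of which the hair gene Tchh alone took 7.16% in P4 library 2 and 14.8% in P10 library 2, and the fibroblast list 1.58 to 4.95%. The skeletal muscle list took 2.80 ± 1.60% at P4, 1.36 ± 1.22% at P10 and 6.23 ± 0.87% at P30. The basal keratinocyte list took 0.731 to 1.19% and the sebocyte list 0.158 to 1.53%. These shares depend on the genes in each list and do not measure how much RNA came from each tissue. The highest sebocyte shares, 1.52% and 1.53%, were in P4 library 4 and P30 library 3, which were also among the 3 libraries with the fewest detected genes.

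**Figure D1:**
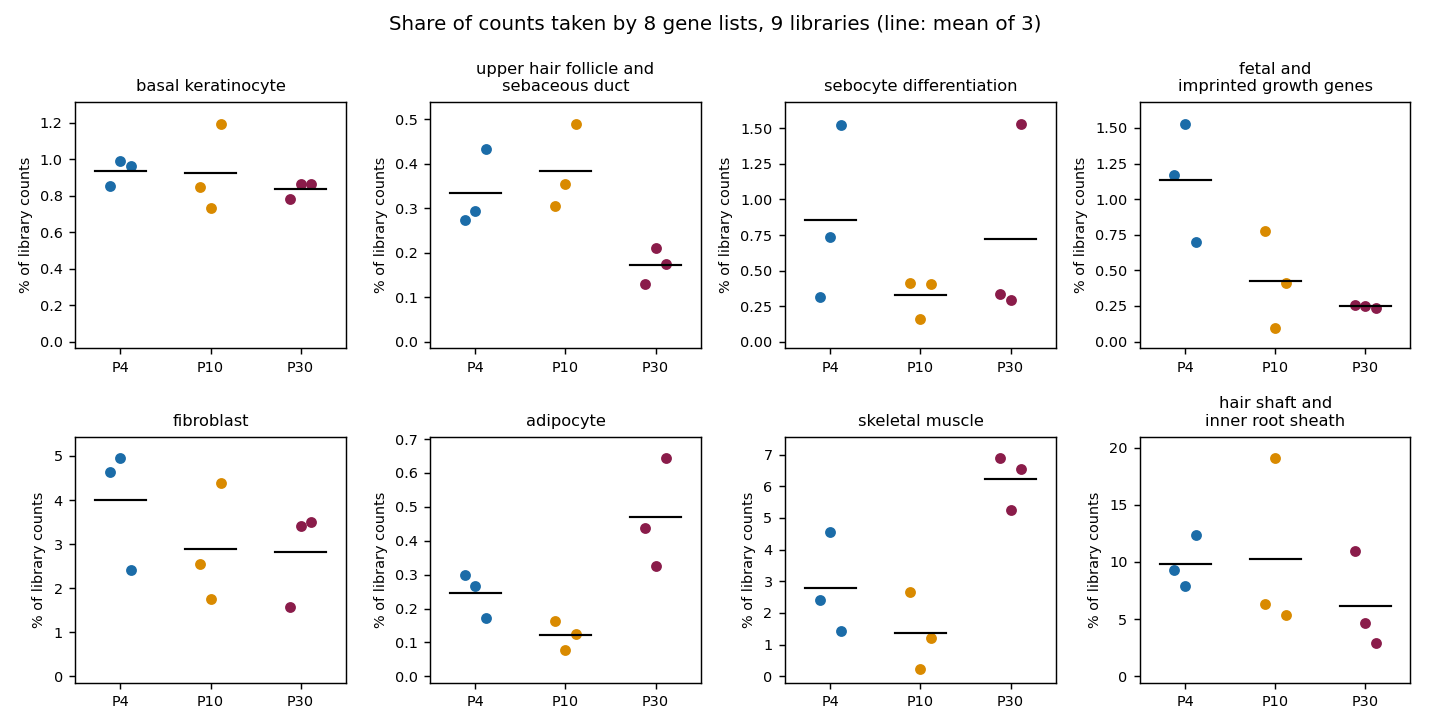
Percent of each library's counts (vertical axis, linear from 0) taken by 8 gene lists at P4, P10 and P30, with 1 point per library and a line at the mean of 3. The skeletal muscle share was 5.24 to 6.88% in the P30 libraries and at most 4.55% in the others, while the fetal and imprinted growth genes took 0.700 to 1.53% at P4 and 0.239 to 0.255% at P30.

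Across the 3 ages, 13 genes changed by the edgeR quasi-likelihood test. The imprinted gene Mest was lower at each later age, with 203 ± 52.8, 63.4 ± 18.2 and 20.2 ± 2.44 CPM (adjusted p = 0.0161). Its neighbour Cpa4, a carboxypeptidase gene, had 193 ± 47.6, 89.5 ± 3.09 and 38.3 ± 7.43 CPM (adjusted p = 0.0202). Atp1b1, a subunit of the sodium pump, had 27.1 ± 1.04, 129 ± 25.8 and 189 ± 46.7 CPM (adjusted p = 0.0161). Plb1, a phospholipase gene, had its highest level at P10, with 6.63 ± 2.5, 90.3 ± 38.3 and 9.54 ± 2.27 CPM (adjusted p = 0.0175). The complement gene C3 had 26.0 ± 21.7, 13.2 ± 4.07 and 257 ± 94.4 CPM (adjusted p = 0.0383). The other 8 genes were C4b, Myh10, Mylk2, Pfkfb3, Pltp, Pvalb, Serpinb6a and Synm. Plb1 and C3 passed no pairwise test and were chosen after their values were seen. DESeq2 called 501 genes across the ages. By edgeR 34 passed without P4 library 2, 1 without P4 library 4 or P30 library 2, 22 without P10 library 1, 25 without P10 library 2, 4 without P10 library 3 and 0 without P30 library 1 or P30 library 3.

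P10 was compared with P4 to follow the gland through its formation. No single gene passed the edgeR test. Genes of fetal growth, of fibroblasts and of lipid metabolism shifted down as groups under camera with the preset correlation. The medians of the lipid groups were -0.14 to 0.075 in the fit without the 3 libraries with the fewest detected genes. That fit leaves P4 library 2 alone at P4. With an estimated correlation 0 of the 33 lists passed (smallest adjusted p = 0.571). Of 17 measured fetal and imprinted growth genes, 17 had a negative fold change and 6 fell when adjusted over the list alone, against 0 over all genes. The list was lower at P10 (median log2 fold change -1.57, camera adjusted p = 1.57e-16), with an adjusted p = 0.571 with an estimated correlation. Mest, whose product is related to hydrolases, had a log2 fold change of -1.68 ± 0.28, and the imprinted transcription factor gene Plagl1 one of -2.17 ± 0.44, with edgeR adjusted p over all genes of 0.225 and 0.326.

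Lipid lists were lower at P10 with all 9 libraries. The sebocyte differentiation list had a median log2 fold change of -1.40 over 20 genes (camera adjusted p = 1.31e-07; adjusted p = 0.63 with an estimated correlation). None of its members passed over all genes or adjusted over the list alone. Elovl3, a fatty acid elongase gene, had a log2 fold change of -2.81 ± 0.84, and the lipid droplet gene Plin2 had 261 ± 119 and 76.8 ± 19.2 CPM. The fatty acid synthesis list was lower over 20 genes (camera adjusted p = 0.0258; adjusted p = 0.63 with an estimated correlation), with 0 members past the threshold either way. Its desaturase gene Fads2 had a log2 fold change of 2.06 ± 0.55 and the elongase gene Elovl7 one of -1.34 ± 0.39. In the cholesterol synthesis list (camera adjusted p = 0.00683; adjusted p = 0.781 with an estimated correlation), 2 of 22 members fell when adjusted over the list alone, among them Hsd17b7 with a log2 fold change of -1.40 ± 0.38. In the fatty acid oxidation and peroxisome list (camera adjusted p = 0.0011; adjusted p = 0.63 with an estimated correlation), 4 of 20 members fell and 1 rose adjusted over the list alone. The dehydrogenase gene Acadm had 141 ± 40.9 and 61.3 ± 11.6 CPM, and Cpt1a, which controls fatty acid entry into mitochondria, had 63.9 ± 23.7 and 133 ± 4.35 CPM. The sebocyte list took 0.316, 0.733 and 1.52% of counts in P4 libraries 2, 3 and 4 and 0.416, 0.158 and 0.404% in P10 libraries 1, 2 and 3, so P4 library 2 lay inside the P10 range. P4 libraries 3 and 4 are among the 3 libraries with the fewest detected genes. A fit without those 3, chosen after seeing the data, leaves P4 library 2 alone at P4, so it compares P10 with 1 library. Its medians were 0.046, 0.068, 0.075 and -0.14 for the sebocyte, fatty acid synthesis, cholesterol and oxidation lists. Scd1 was at 0.016 instead of -1.60. Without P4 library 4 alone the sebocyte median was -0.75 instead of -1.40 (camera adjusted p = 0.0011), and the other 3 lists had medians of -0.26, 0.19 and -0.16 with adjusted p of 0.629, 0.947 and 0.0739, and without P10 library 2 fatty acid synthesis had 0.0928.

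Markers of other cell types moved beside these groups. The fibroblast list was lower at P10, with 6 of 15 members down adjusted over the list alone (camera adjusted p = 8.83e-11; adjusted p = 0.609 with an estimated correlation), among them Pdgfra with a log2 fold change of -1.35 ± 0.20 and Lum with -1.79 ± 0.37. The adipocyte list was lower, with 7 of 11 members down adjusted over the list alone (camera adjusted p = 1.92e-07; adjusted p = 0.609 with an estimated correlation). Its lipid droplet gene Plin1 had 129 ± 7.51 and 45.8 ± 7.02 CPM, and its fatty acid transporter gene Cd36 303 ± 52.1 and 120 ± 45.2 CPM. The skeletal muscle list was lower (camera adjusted p = 9.45e-04; adjusted p = 0.71 with an estimated correlation), with Tnnc2 at -2.05 ± 0.78 and Myh8 at -2.14 ± 0.83. The hair shaft and inner root sheath list was higher, with 21 of 22 fold changes positive (camera adjusted p = 0.0256; adjusted p = 0.781 with an estimated correlation). Without P10 library 2 its median was -0.15 (camera adjusted p = 0.863). It took 6.29, 19.1 and 5.40% of counts in P10 libraries 1, 2 and 3 and 9.30, 7.88 and 12.3% in P4 libraries 2, 3 and 4. Its keratin gene Krt35 had 25.1 ± 32.8 CPM at P4 and 123, 519 and 149 CPM in the P10 libraries, and the homeobox gene Msx2 had 54.1 ± 21.8 and 97.7 ± 37.0 CPM. Without P4 library 2 or 3 the hair list had adjusted p of 0.126 and 0.698, and the muscle list had 0.0839 without P4 library 3 and 0.276 without P10 library 2. Without the 3 libraries with the fewest genes, which leaves P4 library 2 alone at P4, the hair and muscle medians were 0.55 and -0.88. Neither list had a member past the threshold either way.

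Ribosomal protein genes were higher at P10 (camera adjusted p = 3.09e-04; adjusted p = 0.63 with an estimated correlation), with Rps3 at a log2 fold change of 0.81 ± 0.26 and Rpl10 at 0.87 ± 0.29. Nuclear genes of oxidative phosphorylation were lower (camera adjusted p = 9.45e-04; adjusted p = 0.63 with an estimated correlation), with Uqcrfs1 at -1.05 ± 0.33. Glycolysis genes were lower (camera adjusted p = 0.0292; adjusted p = 0.63 with an estimated correlation), with the lactate transporter gene Slc16a3 at -1.92 ± 0.66 and Aldoa at -0.75 ± 0.29, and had an adjusted p of 0.236, 0.0825 and 0.2 without P4 library 2, P4 library 3 or P10 library 2. None of these 3 lists had a member past the threshold over all genes or adjusted over the list alone. The basal keratinocyte list did not pass (camera adjusted p = 0.368, direction down with a median of 0.13), with Col17a1 at 0.97 ± 0.34 and Itgb1 at -0.58 ± 0.23. In all, 12 of 33 lists passed camera and 21 did not. Of 31 member calls adjusted over a list alone, 7 passed without each library in turn, and 11 passed with the muscle covariate described next. With a muscle covariate, the mean log2 CPM of Ttn and Neb, chosen after seeing the data, the fatty acid synthesis list did not pass (adjusted p = 0.101), with a median of -0.58 against -0.62 without the covariate. The glycolysis, hair and muscle lists did not pass either (0.382, 0.262 and 0.543), with medians of -0.12, -0.071 and -0.16 against -0.23, 0.82 and -0.90. Among lists that still passed, the oxidative phosphorylation median was -0.083 against -0.28 (adjusted p = 0.0448), the ribosomal median 0.21 against 0.38 (0.0168) and the fetal median -1.04 against -1.57. Without the 3 libraries with the fewest genes, and so with P4 library 2 alone at P4, the ribosomal, glycolysis and fibroblast medians were 0.17, -0.42 and -1.14 against 0.38, -0.23 and -0.75. For single genes, 1362 had an unadjusted p under 0.05 by edgeR, where the smallest adjusted p was 0.0561, of Atp1b1. DESeq2 called 153 genes, limma-voom 2 and limma-voom with quality weights 0, while edgeR gave 4 calls without P4 library 2, 2 without P4 library 3 or P10 library 3 and 1 without P30 library 2.

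P30 was compared with P10 to set the steady-state gland against the forming one. By the edgeR quasi-likelihood test 3 genes rose and 0 fell, each at an adjusted p = 0.04997, and the ranges of their CPM did not overlap. Synm, the gene of the intermediate filament protein synemin (chromosome 7, 67730161 to 67759742), rose from 57.4 ± 26.9 to 638 ± 121 CPM, a log2 fold change of 3.47 ± 0.42. Pfkfb3, a regulator of glycolysis (chromosome 2, 11471430 to 11554071), rose from 15.3 ± 1.47 to 88.9 ± 34.5 CPM, a log2 fold change of 2.54 ± 0.32. Serpinb6a, a serine protease inhibitor gene (chromosome 13, 33917918 to 34002794) of a family of close paralogs, rose from 65.3 ± 11.8 to 291 ± 29.4 CPM, a log2 fold change of 2.16 ± 0.25. The skeletal muscle list took 1.36 ± 1.22% of counts at P10 and 6.23 ± 0.87% at P30. With the mean log2 CPM of the muscle genes Ttn and Neb as a covariate, chosen after seeing the data, the 3 calls ended. Synm was then at 2.37 ± 0.37 (adjusted p = 0.146), Pfkfb3 at 2.41 ± 0.55 (0.851) and Serpinb6a at 1.65 ± 0.34 (0.491). The Ttn levels of P10 and P30 did not overlap, so this fit cannot separate age from muscle RNA. Ranges that do not overlap are found in 10% of unselected genes by chance. The 3 genes were selected by a test on the same libraries, so their separation adds no support.

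Gland and follicle lists moved in both directions. Of 10 measured genes of the upper hair follicle and sebaceous duct, 6 fell adjusted over the list alone and 0 over all genes, with Lrig1 at a log2 fold change of -0.94 ± 0.25 and Lgr6, a stem cell receptor gene, at -1.55 ± 0.50 (camera adjusted p = 1.72e-08; adjusted p = 0.128 with an estimated correlation). The basal keratinocyte list was lower over 17 genes (camera adjusted p = 0.0254; adjusted p = 0.475 with an estimated correlation), with Krt5 at -0.73 ± 0.25 and Plec, which links keratin to integrins, at 0.74 ± 0.28. The basal list had adjusted p of 0.291 without P10 library 3 and 0.109 without P30 library 3. The sebocyte list did not pass camera (adjusted p = 0.0655), while 2 of its members rose adjusted over the list alone. These were Dgat2, which makes triglycerides, at 2.01 ± 0.30 and the lipid droplet gene Cidec at 1.90 ± 0.43. The fatty acid synthesis list was higher (camera adjusted p = 8.05e-04; adjusted p = 0.378 with an estimated correlation). Fasn rose adjusted over that list alone, from 545 ± 72.9 to 1982 ± 1245 CPM, with 1529, 1027 and 3391 CPM in P30 libraries 1, 2 and 3, and Me1 had a log2 fold change of 1.47 ± 0.47. The list took 0.610, 0.512 and 2.0% of counts in P30 libraries 1, 2 and 3 and 0.589, 0.299 and 0.564% in P10 libraries 1, 2 and 3. Without P30 library 3, which is among the 3 with the fewest genes, the list median was 0.32 instead of 0.88 (camera adjusted p = 0.0165), and Pparg was at -0.013 instead of 0.97. Fasn was then at 1.23, with an edgeR adjusted p over the list alone of 0.104, and without P10 library 1, 2 or 3 that p was 0.0982, 0.124 and 0.119. Fatty acid oxidation genes were higher (camera adjusted p = 0.00981; adjusted p = 0.475 with an estimated correlation), with Acadm at 1.04 ± 0.30 and Acadvl at 0.60 ± 0.20, but not without P30 library 3 (adjusted p = 0.221). Cidec had an adjusted p over its list of 0.0527 without P10 library 2.

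Genes of the cell cycle were lower at P30 than at P10. All 22 measured S phase genes had a negative fold change, with a median of -0.60 (camera adjusted p = 1.46e-06; adjusted p = 0.259 with an estimated correlation), among them Pcna at -0.88 ± 0.30 and Uhrf1 at -0.61 ± 0.25. The G2 and mitosis list had 19 of 22 negative fold changes (camera adjusted p = 3.59e-05; adjusted p = 0.33 with an estimated correlation), with Kif11 at -0.59 ± 0.20 and Cdk1 at -1.01 ± 0.35. No member of either list passed over all genes or adjusted over the list alone. Of the fetal and imprinted growth genes 4 of 17 fell adjusted over the list alone (camera adjusted p = 0.0169; adjusted p = 0.479 with an estimated correlation), with Mest at -1.65 ± 0.29 and the RNA-binding protein gene Igf2bp3 at -3.44 ± 0.64. That list had camera adjusted p of 0.471, 0.106, 0.165 and 0.118 without P10 library 1, P10 library 3, P30 library 1 or P30 library 2. Ribosomal protein genes had a negative fold change in 24 of 24 cases, with a median of -0.29 (camera adjusted p = 3.96e-06; adjusted p = 0.378 with an estimated correlation), with Rps18 at -0.46 ± 0.21 and Rps4x at -0.35 ± 0.21. No ribosomal member passed over all genes or adjusted over the list alone.

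Energy metabolism genes were higher at P30, as was the skeletal muscle share of counts. Of 16 glycolysis genes, 10 rose adjusted over the list alone and 0 over all genes (camera adjusted p = 3.63e-11; adjusted p = 0.128 with an estimated correlation; fry adjusted p = 0.0258). Aldoa had 648 ± 89.7 CPM at P10 and 2235 ± 365 at P30, and Ldha 182 ± 29.6 and 420 ± 53.2 CPM. All 24 measured nuclear genes of oxidative phosphorylation had a positive fold change (camera adjusted p = 2.41e-10; adjusted p = 0.13 with an estimated correlation), with Cox6c at 0.85 ± 0.25 and Uqcrc1 at 0.68 ± 0.21. With the muscle covariate the oxidative phosphorylation median was 0.26 against 0.55 (camera adjusted p = 0.00565) and the glycolysis median 0.77 against 1.01 (3.76e-07). The interferon response and MHC class I list had 19 of 19 positive fold changes and 3 members that rose adjusted over the list alone (camera adjusted p = 7.85e-10; adjusted p = 0.128 with an estimated correlation), with B2m, the light chain of MHC class I, at 1.68 ± 0.42 and Oasl2 at 3.84 ± 0.89. The list took 0.040, 0.079 and 0.11% of counts in P30 libraries 1, 2 and 3. P30 library 1 lay inside the P10 range of 0.028 to 0.042%. The signalling lists that follow were lower, with no member past the threshold either way. These were the Wnt list (camera adjusted p = 4.63e-04; adjusted p = 0.378 with an estimated correlation; Dkk3 at -1.13 ± 0.35, Lgr4 at -0.50 ± 0.25) and the EGFR list (camera adjusted p = 0.0133; adjusted p = 0.502 with an estimated correlation; Erbb3 at -0.78 ± 0.29, Erbb2 at -0.36 ± 0.19). The last was the TGF-beta and BMP list (camera adjusted p = 0.0185; adjusted p = 0.475 with an estimated correlation), with Bmpr1a at -0.41 ± 0.20 and Bmp7 at -0.66 ± 0.33. Without P30 library 3 these 3 lists had adjusted p of 0.0541, 0.175 and 0.0927. Without P10 library 2 the EGFR list had 0.0589 and the TGF-beta list 0.113, and the latter had 0.0501 without P30 library 1.

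Markers of 8 other cell types moved as well. Of 12 skeletal muscle genes, 11 rose adjusted over the list alone (camera adjusted p = 8.17e-21; adjusted p = 0.128 with an estimated correlation), with the fast myosin gene Myh4 at 348 ± 313 and 15710 ± 997 CPM and Actn3 at 136 ± 124 and 1014 ± 283 CPM. Of 11 adipocyte genes, 10 rose adjusted over the list alone (camera adjusted p = 1.59e-15; adjusted p = 0.128 with an estimated correlation), with Plin1 at 2.22 ± 0.35 and Car3 at 3.04 ± 0.50. The immune list was higher with 2 of 17 members (camera adjusted p = 8.13e-06; adjusted p = 0.378 with an estimated correlation), C1qa at 2.28 ± 0.48 and Cd68 at 2.23 ± 0.60, which rose adjusted over the list alone. The list took 0.026, 0.089 and 0.057% of counts in P30 libraries 1, 2 and 3. P30 library 1 lay inside the P10 range of 0.019 to 0.041%. The fibroblast list was higher (camera adjusted p = 0.00194; adjusted p = 0.479 with an estimated correlation), with Pi16 at 3.32 ± 0.61, which rose adjusted over the list alone, and Dpt at 1.40 ± 0.44. The smooth muscle list was higher (camera adjusted p = 0.0308; adjusted p = 0.479 with an estimated correlation), where Lmod1 at 2.61 ± 0.76 and Des at 2.02 ± 0.64 rose adjusted over the list alone. The endothelial list was higher (camera adjusted p = 0.00809; adjusted p = 0.479 with an estimated correlation), with Pecam1 at 0.80 ± 0.34. Vwf, at 2.37 ± 1.15, had 31.5, 367 and 5.43 CPM in P30 libraries 1, 2 and 3 and was at -0.50 without P30 library 2. The hair shaft list was lower, with a negative fold change in 22 of 22 genes (camera adjusted p = 8.13e-06; adjusted p = 0.479 with an estimated correlation), among them Krt72 at -2.66 ± 0.99 and Padi3 at -1.39 ± 0.53. No hair member passed over all genes or adjusted over the list alone. The interfollicular suprabasal list was lower (camera adjusted p = 0.0191; adjusted p = 0.502 with an estimated correlation), with Ivl at -1.28 ± 0.66 and Dsc1 at -0.67 ± 0.49. Without P10 library 2 the fibroblast, smooth muscle, endothelial, hair and suprabasal lists had adjusted p of 0.16, 0.113, 0.0853, 0.0522 and 0.181. Without P30 library 3 the fibroblast, smooth muscle and suprabasal lists had 0.105, 0.146 and 0.357, and without P30 library 2 the smooth muscle and endothelial lists had 0.219 and 0.133. The smooth muscle list had 0.0547 without P10 library 1, and the suprabasal list had 0.282 (median 0.28) without P10 library 3 and 0.113 without P30 library 1.

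Together 22 of 33 lists passed camera for P30 versus P10 and 11 did not. Of 55 member calls adjusted over a list alone, 24 passed without each library in turn, and 7 passed with the muscle covariate. In this comparison Ttn had 1020 to 18600 CPM at P10 and 38200 to 55200 at P30, so the ages share no range of it. Fits with the muscle covariate therefore extrapolate here and cannot separate age from muscle RNA. With the muscle covariate the hair shaft list was higher at P30 instead of lower (median 0.99 against -1.28, camera adjusted p = 2.77e-07). The fatty acid oxidation (adjusted p = 0.425), ribosomal (0.741), Wnt (0.238), TGF-beta (0.847), EGFR (0.519), suprabasal (0.232), fibroblast (0.427), endothelial (0.232) and smooth muscle (0.995) lists did not pass. Their medians, in that order, were 0.17, 0.025, -0.016, 0.13, 0.13, -0.083, -0.40, -0.24 and 0.042 against 0.43, -0.29, -0.48, -0.57, -0.36, -0.41, 0.24, 0.66 and 0.32 without the covariate. Among lists that still passed, the median was 0.50 against 0.88 for fatty acid synthesis (adjusted p = 0.0459), 1.24 against 1.91 for adipocyte, 0.47 against 2.47 for skeletal muscle (0.00862) and -1.92 against -0.80 for the fetal genes. Without the 3 libraries with the fewest genes, the basal (0.147), fatty acid oxidation (0.211), TGF-beta (0.118), EGFR (0.215), suprabasal (0.428), fibroblast (0.165) and smooth muscle (0.215) lists did not pass, and the mitosis, Wnt and hair medians were -0.33, -0.27 and -0.84 against -0.50, -0.48 and -1.28. For single genes edgeR gave 942 at an unadjusted p under 0.05, DESeq2 called 236, and limma-voom called 43. The 3 edgeR calls became 0 without P4 library 2, P4 library 4, P10 library 2 or any 1 P30 library, and 1 lower gene without P10 library 3, where the 3 genes had adjusted p of 0.236 to 0.306. Without P4 library 3 they became 5 higher and 2 lower, and without P10 library 1 Synm passed (adjusted p = 0.0494) but Pfkfb3 (0.0885) and Serpinb6a (0.0598) did not. A fit of the 4 libraries numbered S2 to S5 in the titles, which hold both ages, called 0 genes and kept the sign of all 3.

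P30 was compared with P4, the widest span of ages. By the edgeR quasi-likelihood test 8 genes rose and 6 fell, and for all 14 the CPM ranges of the ages did not overlap. Chance gives this in 10% of unselected genes. These 14 were selected by a test on the same libraries, so their separation adds no support. The smallest adjusted p were those of Mest (chromosome 6, 30733506 to 30748466), which fell 10.1-fold (log2 fold change -3.33 ± 0.30, adjusted p = 0.00429), and Atp1b1 (chromosome 1, 164437099 to 164458355), which rose 6.98-fold (2.80 ± 0.26, adjusted p = 0.00429). Cpa4 (chromosome 6, 30568369 to 30592418) fell 5.03-fold (-2.33 ± 0.25, adjusted p = 0.0113). The complement gene C4b, on chromosome 17 beside its near-identical copy C4a, rose from 2.01 ± 1.76 to 176 ± 57.8 CPM (6.42 ± 0.83, adjusted p = 0.0442). Mest and Atp1b1 passed without each library in turn, whereas Cpa4 had an adjusted p of 0.0566, 0.0537 and 0.0621 without P30 library 1, 2 or 3. C4b had 0.0625, 0.0927 and 0.139 without the same libraries, 0.129 without P4 library 4 and 0.107 without P10 library 3.

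The other 10 calls had an adjusted p = 0.049 in the edgeR test, and none of the 10 passed without P4 library 4, P10 library 3 or any 1 P30 library (adjusted p 0.0522 to 0.199). Without P4 library 3 Lyz1 and Synm passed, without P10 library 1 Pvalb, Mylk2, Synm, Atp1b4 and Nrk did, and without P4 library 2 Mylk2 did not (0.0582). Genes of muscle were among the 10 in both directions. Pvalb, a calcium buffer of fast muscle, rose from 0.509 ± 0.882 to 587 ± 79.2 CPM. Its 26 counts at P4 were all in P4 library 2, without which the fitted log2 fold change was 16.05 instead of 10.05 and is no bound. Mylk2, a myosin kinase of skeletal muscle, rose from 9.79 ± 1.11 to 126 ± 8.33, and Synm rose from 81.1 ± 34.2 to 638 ± 121. Atp1b4, whose product is known from perinatal muscle, fell from 357 ± 250 to 7.12 ± 2.10 CPM. Nrk, a kinase gene of embryonic tissue, fell from 199 ± 78.9 to 12.6 ± 3.84 CPM, the non-muscle myosin gene Myh10 from 354 ± 19.1 to 142 ± 7.06, and the collagen gene Col12a1 by 1.81 ± 0.26 on the log2 scale. The hepcidin gene Hamp2 and the lysozyme gene Lyz1 had 0 counts in the P4 libraries, and at P30 they had 35.7 ± 38.8 and 17.0 ± 5.91 CPM, at least 534-fold and at least 254-fold higher than a floor of 3 counts over the P4 libraries. Hamp2 had 79.9 CPM in P30 library 3 and 19.7 and 7.44 in P30 libraries 1 and 2, and its adjusted p was 0.168 without library 3. Each has a close paralog, so reads may be split between copies. Pltp, a phospholipid transfer protein gene outside the naming rule and chosen after its values were seen, rose from 15.8 ± 3.04 to 84.3 ± 29.3 CPM.

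**Figure D2:**
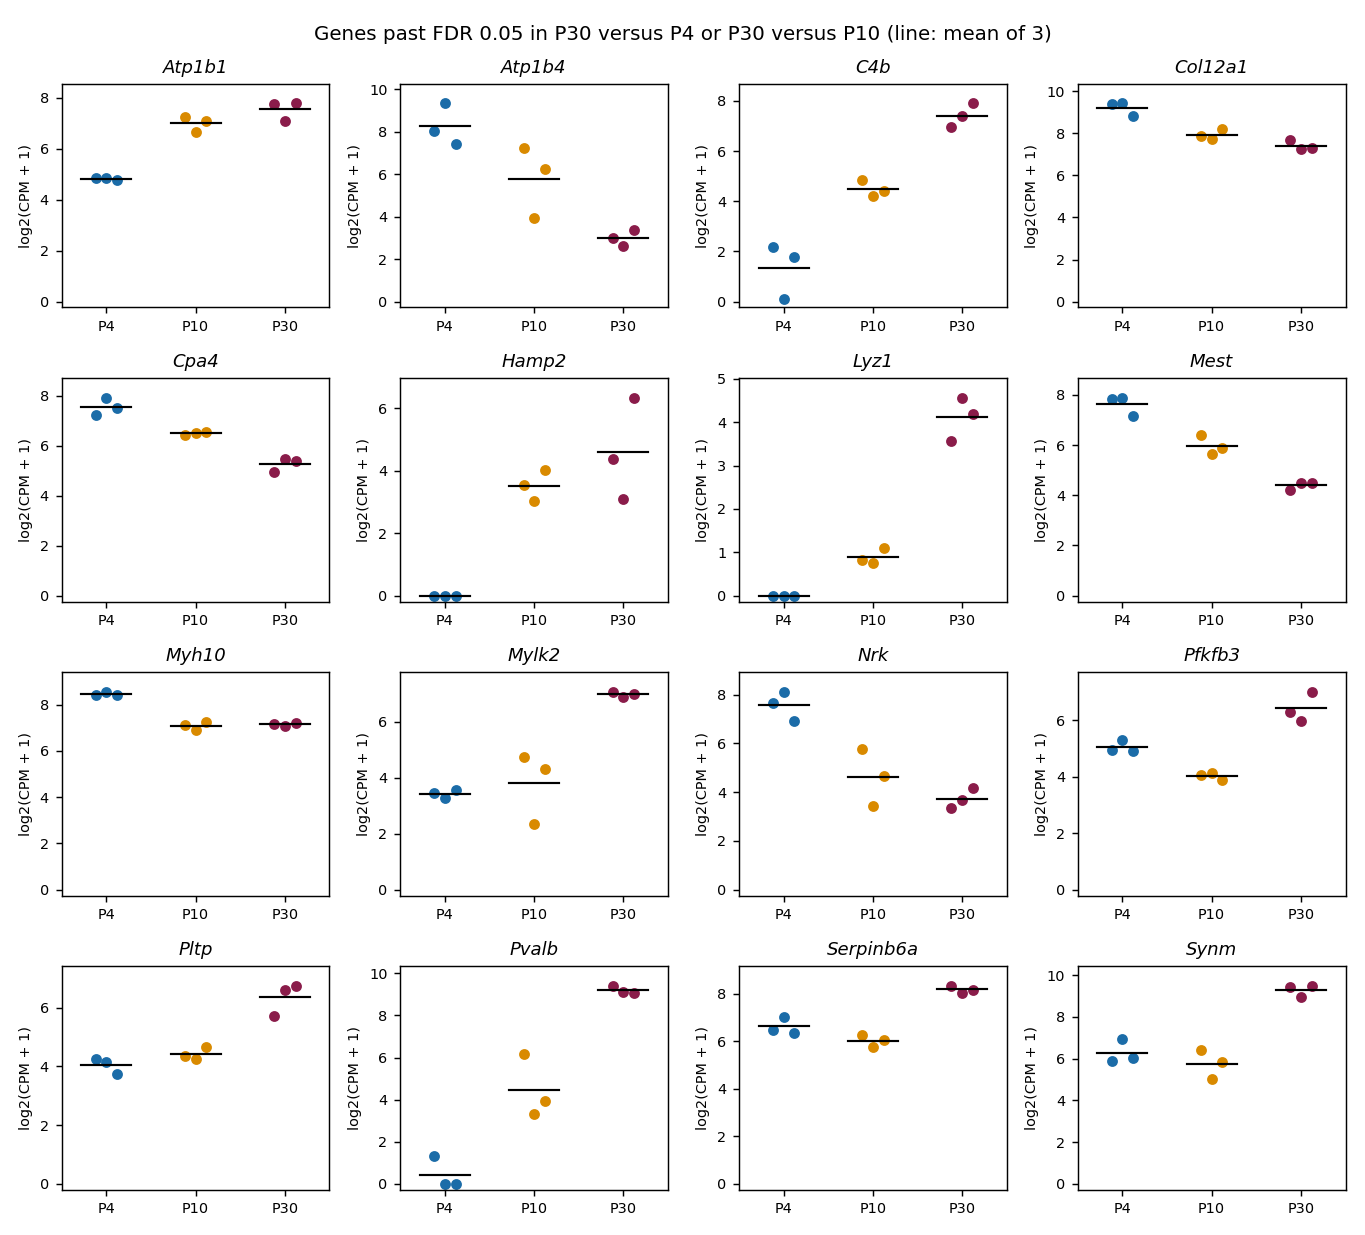
Level of the 16 genes past the threshold in P30 versus P4 or P30 versus P10, as log2(CPM + 1) on the vertical axis, with 1 point per library and a line at the mean of 3. Mest and Cpa4 are lower at each later age, Atp1b1 and C4b are higher, and Hamp2 and Lyz1 lie at 0 at P4.

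Fetal and imprinted growth genes were lower at P30. Of 17 measured members, 17 had a negative fold change, 14 fell adjusted over the list alone and 1, Mest, over all genes (median -2.28, camera adjusted p = 8.22e-18; adjusted p = 0.374 with an estimated correlation). Igf2 had 1650 CPM at P4, 549 at P10 and 81.5 at P30, and Dlk1 had 336, 95.2 and 1.80. Both were chosen after their values were seen and fell adjusted over the list alone. Beside this list, the fibroblast list was lower (median -0.45, camera adjusted p = 2.09e-04; adjusted p = 0.545 with an estimated correlation), with 3 members down and 1 up adjusted over the list alone. Pdgfra had a log2 fold change of -1.03 ± 0.20 and Twist2 one of -2.42 ± 0.55. The fibroblast median was -0.19 without P30 library 1 (camera adjusted p = 0.114), -0.22 without P4 library 3, -0.71 without P4 library 4 and -0.73 with the muscle covariate. It was -0.79 without the 3 libraries with the fewest genes, which leaves P4 library 2 alone at P4.

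Upper follicle and sebaceous duct genes were lower (camera adjusted p = 8.57e-05; adjusted p = 0.374 with an estimated correlation), and 2 of 10, Lrig1 at -0.88 ± 0.25 and Lgr6 at -1.91 ± 0.50, fell adjusted over the list alone. The sebocyte list was lower (median -0.75, camera adjusted p = 0.001; adjusted p = 0.776 with an estimated correlation), while Dgat2, at 1.54 ± 0.30, rose adjusted over the list alone and Krt7 had a log2 fold change of -2.91 ± 0.96. The sebocyte median was 0.041 without P4 library 4 (camera adjusted p = 0.118), -0.35 without P30 library 2 (0.0879), -0.32 without P30 library 1, -2.20 without P30 library 3, -1.16 without P4 library 2 and -1.45 with the muscle covariate. The basal keratinocyte list was lower in 13 of 17 genes (camera adjusted p = 0.00462; adjusted p = 0.473 with an estimated correlation), with the integrin gene Itga6 at -0.82 ± 0.28. The bulge list, of the stem cell niche of the lower follicle, was lower (camera adjusted p = 0.0403; adjusted p = 0.473 with an estimated correlation), with Foxc1 at a log2 fold change of -0.99 ± 0.41 and Postn with 1158 ± 494 CPM at P4 and 578 ± 260 at P30. The bulge list had adjusted p of 0.372 and 0.162 without P4 library 2 or P30 library 1. S phase genes were lower in 20 of 22 cases (camera adjusted p = 8.57e-05; adjusted p = 0.473 with an estimated correlation), with Mcm4 at -0.86 ± 0.23 and Prim1 at -1.29 ± 0.46. G2 and mitosis genes were lower in 19 of 22 (camera adjusted p = 5.18e-06; adjusted p = 0.389 with an estimated correlation), with Ccna2 at -0.77 ± 0.22 and Kif11 at -0.68 ± 0.20. None of the basal, bulge and cell cycle genes passed over all genes or adjusted over the list alone.

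Immune, muscle and fat lists were higher at P30. Of 19 interferon and MHC class I genes, 6 rose adjusted over the list alone (camera adjusted p = 5.18e-06; adjusted p = 0.374 with an estimated correlation), with H2-K1 at 45.3 ± 12.8 and 205 ± 73.4 CPM and Ifit1 at 0.039 ± 0.068 and 11.9 ± 13.4 CPM. Of 17 immune cell genes, 6 rose adjusted over the list alone (camera adjusted p = 1.15e-04; adjusted p = 0.473 with an estimated correlation), with the MHC class II gene H2-Ab1 at 3.72 ± 0.71 and C1qa at 1.81 ± 0.47. The immune list took 0.026% of counts in P30 library 1, inside the P4 range of 0.011 to 0.030%. Of 16 glycolysis genes, 6 rose adjusted over the list alone (camera adjusted p = 7.49e-05; adjusted p = 0.374 with an estimated correlation), with Pkm at 1.07 ± 0.26 and Ldha at 0.90 ± 0.23. Of 12 skeletal muscle genes, 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.18e-06; adjusted p = 0.473 with an estimated correlation). Actn3 had a log2 fold change of 3.17 ± 0.65 and Myh4 one of 4.06 ± 0.85. The member that fell was Myh8, the perinatal myosin gene chosen after its values were seen, with 14360 CPM at P4 and 1506 at P30. Of 11 adipocyte genes, 3 rose adjusted over the list alone (camera adjusted p = 0.0403; adjusted p = 0.8 with an estimated correlation), with Cfd at 1.93 ± 0.39 and Car3 at 1.72 ± 0.48. The adipocyte list had an adjusted p of 0.164, 0.228 and 0.625 without P4 library 2, P4 library 4 or P30 library 3. None of these 5 lists had a member past the threshold over all genes.

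In P30 versus P4, 13 of 33 lists passed camera and 20 did not. Of 61 member calls adjusted over a list alone, 29 passed without each library in turn, and 35 passed with the muscle covariate. Among the fits chosen after seeing the data, that without the 3 libraries with the fewest genes leaves P4 library 2 alone at P4. Its basal, sebocyte and adipocyte medians were -0.13, -0.67 and 0.096 against -0.41, -0.75 and 0.89. With the muscle covariate the adipocyte and skeletal muscle lists had 0.748 and 0.0999, with medians of 0.47 and 0.68 against 0.89 and 1.83. The upper follicle and bulge lists passed with medians of -0.45 and -0.40 against -0.73 and -0.66. Without P4 library 4 these 2 medians were -0.37 and -0.39, and without P4 library 2 the bulge median was -0.18. For single genes edgeR gave 1537 at an unadjusted p under 0.05, DESeq2 called 451 and limma-voom called 22. The fit without the 3 libraries with the fewest detected genes leaves P4 library 2 alone at P4, so its count of calls is not given. Without P4 library 2 the edgeR calls numbered 89, without P10 library 2 49, and without P4 library 4, P10 library 3 or P30 library 3 they numbered 3. Without P30 library 1 or P30 library 2 they numbered 2, and of the 12 without P4 library 3 and the 10 without P10 library 1, 6 and 9 were among the 14.

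**Figure D3:**
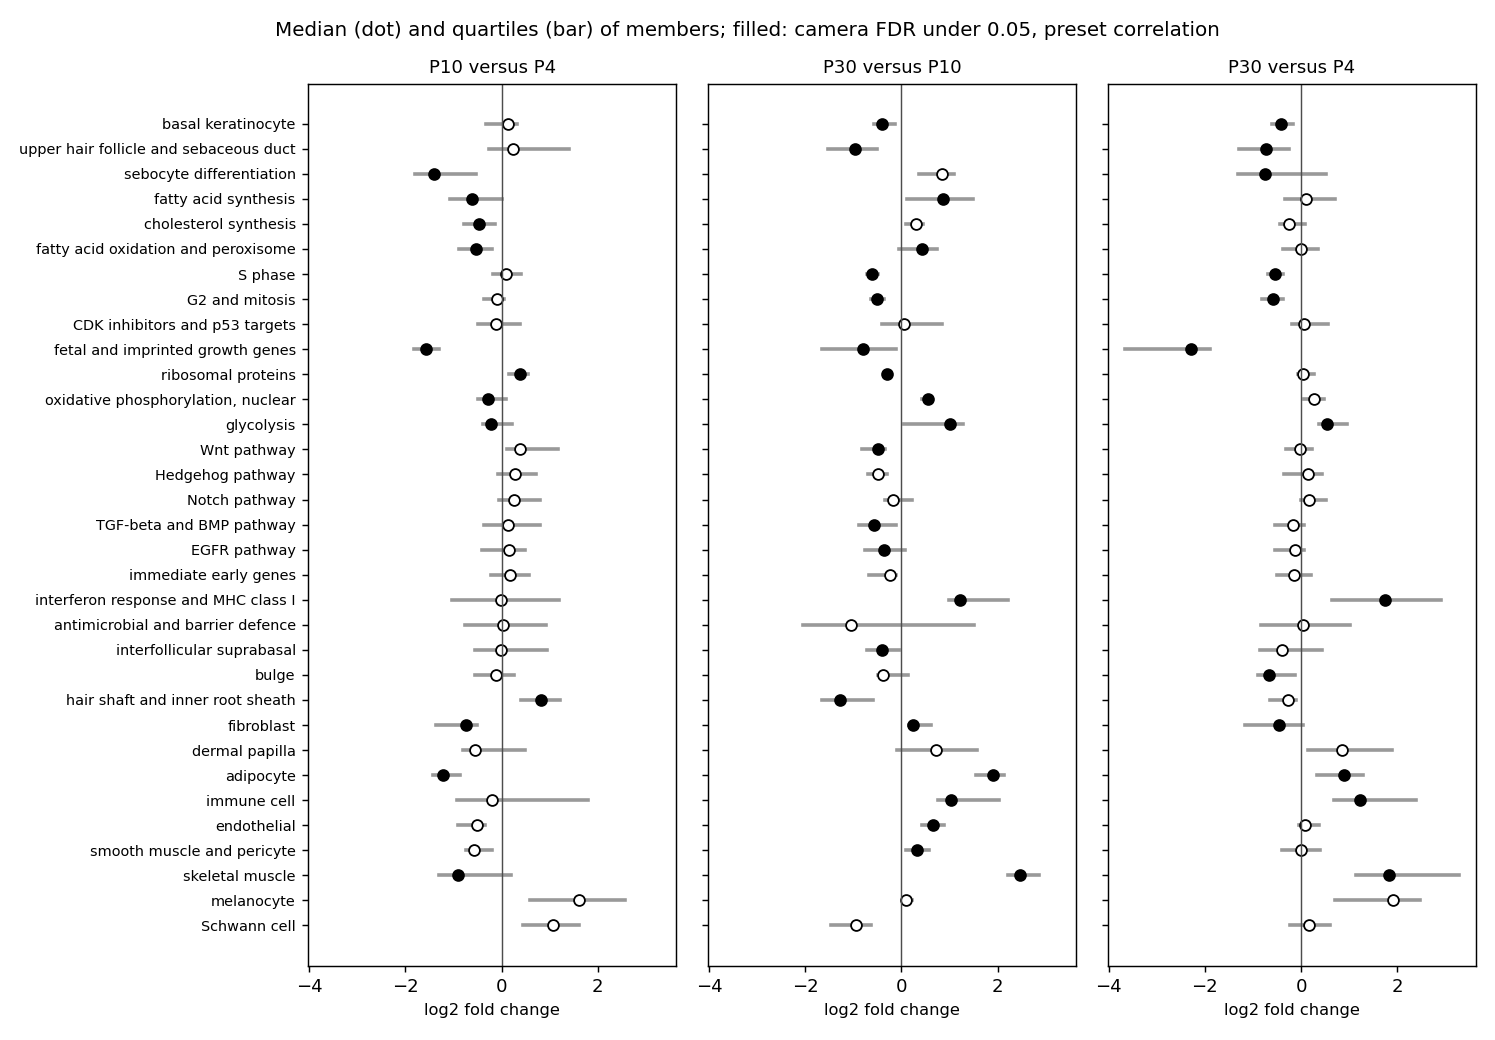
Median log2 fold change (dots) and quartiles (bars) of the members of 33 gene lists in each pair of ages, on the horizontal axis, with filled dots where camera with the preset correlation gave an adjusted p under 0.05. Filled dots number 12, 22 and 13, and with an estimated correlation 0 lists passed in each comparison.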

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

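The fits without the 3 libraries with the fewest detected genes, without Rn45s, muscle and hair genes, with the muscle covariate, with robust estimation and of libraries S2 to S5 were chosen after seeing the data. The 14 calls of P30 versus P4 and the 3 of P30 versus P10 kept their sign in every setting run, and the 14 passed with DESeq2 and with no filter. Of 3058 values of named genes under the alternatives, 2732 stayed on their side of the threshold with their sign, 196 lost it, 100 gained it and 30 changed sign, in genes uncalled in the main analysis. Of the 3058 values, 2664 belonged to genes uncalled in the main analysis, which had no call to lose. All 196 losses therefore fell on the 17 called results. For P30 versus P4, Mest passed in 21 of 23 settings, Atp1b1 in 20 and Cpa4 in 18, but Hamp2 and Pltp in only 8. For P30 versus P10, Synm and Serpinb6a passed in 11 of 24 settings and Pfkfb3 in 9. Calls across the 3 ages numbered 13, and calls at P30 against P10 and P4 numbered 3 and 0 and 8 and 6 (higher and lower). Leaving out each library gave 0 to 34 genes across ages, 0 to 4 higher and 0 lower for P10 versus P4, 0 to 5 and 0 to 2 for P30 versus P10, and 1 to 59 and 1 to 30 for P30 versus P4. Given below as genes across ages, then higher and lower for P10 versus P4, P30 versus P10 and P30 versus P4, DESeq2 gave 501, 90 and 63, 197 and 39, and 292 and 159. No filter gave 237, 14 and 16, 88 and 22, and 86 and 73. Limma-voom gave 52, 1 and 1, 40 and 3, and 15 and 7, and with quality weights 7, 0 and 0, 261 and 46, and 0 and 2. Library totals alone gave 5, 2 and 0, 0 and 0, and 1 and 2. Upper quartile factors gave 1 and 2 for P30 versus P4, and the stricter filter 0 higher for P30 versus P10 and 5 higher for P30 versus P4. The test against a fold of 1.5 gave 0 higher for P30 versus P10 and 2 and 2 for P30 versus P4, and a fit of the compared ages alone gave 1 lower for P30 versus P10 and 11 lower for P30 versus P4. Of the alternatives chosen after seeing the data, the fit without the 3 libraries with the fewest genes gave 5 and 4 for P30 versus P10. It leaves P4 library 2 alone at P4, so its counts against P4 and across ages are not given. The muscle covariate gave 32, 1 higher for P10 versus P4, 0 and 3 for P30 versus P10, and 38 lower for P30 versus P4, where 12 of the 14 calls passed. Robust estimation gave 2 and 1 for P10 versus P4, and libraries S2 to S5 gave 0 higher for P30 versus P10. With an estimated correlation 0 lists passed in each comparison, and with fry 0, 1 and 0. Same-numbered libraries showed no clear shared deviation (7 pairs, correlations -0.034 to 0.13, 1 above 0.1, and 4 of 8 libraries closest to their own number). The numbers were therefore not taken as pairs. With 3 libraries per age this check is weak, so pairing is not excluded. With the replicate block the calls were 0 across ages, 1 higher for P30 versus P10, and 0 and 0 for P30 versus P4. Sign changes in log2 fold change for P10 versus P4 were, with quality weights, Lrig1 -0.061 and Prdm1 -0.041; with the replicate block, Krt14 0.17, Mki67 -0.053 and Gata6 0.82; without the 3 libraries, Lrig1 -0.059, Krt14 0.55, Scd1 0.016 and Gata6 0.15; and with the muscle covariate, Prdm1 -0.51. For P30 versus P10 they were Pparg -0.010 without the 3 libraries, and with the muscle covariate Prdm1 0.062, Bmp7 0.075, Dsc1 0.87 and Padi3 0.21. For P30 versus P4 Scd1 was -0.089 with limma-voom, -0.41 with quality weights and -0.54 with the muscle covariate. Leave-one-out ranges of the genes that changed sign were for P10 versus P4, Lrig1 -0.19 to 0.22, Krt14 -0.48 to 0.090, Mki67 -0.030 to 0.23, Prdm1 -0.43 to 0.78; for P30 versus P10, Pparg -0.013 to 1.37, Gata6 -1.08 to 0.43, Vwf -0.50 to 2.93; for P30 versus P4, Scd1 -1.12 to 0.76. The cause of these moves was not tested, except that a stricter filter tests fewer genes and a fit without libraries has fewer samples. The alternative without mitochondrial-encoded genes was not run, since the counts held none. Depth and the number of genes a library detects limit genes near 0 counts, such as Hamp2 and Lyz1 at P4. The P4 libraries were not the shallowest. At equal depth P4 libraries 2, 3 and 4 detected 15553, 12093 and 12974 genes, and P30 libraries 1, 2 and 3 detected 16830, 17079 and 13750.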

Other observations

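The tests of the ratio of myosin genes, of fibroblast and muscle levels and the genes near Mest beside the fetal list, and of the age-centred number of detected genes were chosen after the result was seen, as were the genes named here. The signal receptor gene Notch1 had 266 CPM at P4, 538 at P10 and 479 at P30, and its ligand gene Jag1 had 55.6, 161 and 177 CPM. In P10 versus P4 both rose adjusted over the Notch list alone (edgeR adjusted p = 0.0356 and 0.0142), while neither passed over all genes (0.49 and 0.365). The imprinted cell cycle inhibitor gene Cdkn1c had 228, 53.6 and 49.2 CPM and fell from P4 to P10 adjusted over its list alone (edgeR adjusted p = 0.00867), with 0.326 over all genes. Neither list passed camera in P10 versus P4, with adjusted p of 0.0702 for the Notch list and 0.368 for the list of Cdkn1c.

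Xist, expressed from the inactive X chromosome of females, had 1029 CPM in P4 library 4, 969 in P10 library 2, 851 in P30 library 2 and 887 in P30 library 3. The Y-linked gene Ddx3y had 0.065, 0.16 and 0 CPM in the first 3 of these and 14.9 in P30 library 3. In the other 5 libraries Ddx3y had 64.5 to 115 CPM and Xist 0 to 48.0 CPM, the highest in P10 library 3. High Xist was thus found in more libraries at P30 than at P4 or P10, and no fit included sex. P30 library 3 held transcripts of both kinds, and the labels do not say whether it pools animals.

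A ratio of muscle transcripts within each library separated the ages. The mean log2 ratio of Myh8, the perinatal myosin gene, to the titin gene Ttn was -0.18 ± 0.03 at P4, -1.55 ± 0.08 at P10 and -4.96 ± 0.26 at P30 (SD, n = 3). More skeletal muscle RNA at P30 would move both genes by 1 factor and leave the ratio equal, and the tables argue against that as the whole account, since the ratio differed by -4.78 between P30 and P4. A library of another age than its label would lie inside the range of another age, and 0 libraries did. A change of muscle with age may underlie the ratio, as a hypothesis, and a different muscle type captured at each age was not tested.

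The 17 fetal and imprinted growth genes were lower at P30 than P4. Fewer fibroblasts at P30 would lower the fetal and fibroblast lists together, but the difference of their mean log2 CPM changed by -2.56, from -1.83 ± 0.28 to -4.40 ± 0.63 (SD, n = 3). At P10 it was -2.71 ± 0.81, with P10 library 1 at -1.79 inside the P4 range, so fewer fibroblasts stay open for the lower fetal list at P10. Less muscle RNA at P30 would lower Ttn, which was 1.67 higher on the log2 scale. Ttn cannot decide on perinatal muscle, since the ratio of Myh8 to Ttn differed by age. Myh8 had 8220 to 24500 CPM at P4, 335 to 6750 at P10 and 1200 to 1810 at P30. The fetal mean log2 CPM was 6.54 to 7.51, 4.11 to 6.18 and 3.95 to 4.21 at these ages. Less perinatal muscle at P30 therefore stays open. Of 10 other tested genes within 500 kb of Mest, 1, Cpa4, was called. Their median log2 fold change was -0.32, which argues against a fall of the whole neighbourhood. A lower level in cells of the gland and in other cells of the captured tissue may both contribute, and age itself stays open as the design's own difference.

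Libraries with a higher S number in their titles had fewer detected genes (Pearson r = -0.965, exact permutation p = 6.61e-05; Spearman rho = -0.917, exact permutation p = 0.00131; n = 9). At an equal depth of 10018141 counts r was -0.953 (exact permutation p = 0.00011, adjusted over 2 relations 0.00011; rho = -0.917, p = 0.00131, n = 9) and -0.932 without the 2 libraries farthest from the median number, which argues against library size. Age alone is argued against too, since the age-centred r was -0.912, and r was -0.906, -0.881 and -0.975 within P4, P10 and P30, with 3 libraries each and no test. Input amount or capture session may differ with the number, and no label gives either. The P4 libraries are numbered 8, 12 and 13, and of the others only P10 library 3 and P30 library 3, numbered 9 and 10, lie in that range.

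Other splits of the libraries were counted for each comparison. For the 3 ages, the 9 libraries were split in 100 of 280 possible ways, the real one included. Of these, 2 gave at least the 13 genes of the real split, a share of 0.02, and the highest other gave 31. Random splits thus seldom gave as many genes. The share cannot tell age from another difference between the libraries, such as the S number, and it treats the libraries as independent. The split with 31 genes kept the 3 P30 libraries together and mixed P4 with P10. Its sets did not overlap in the muscle gene Ttn, with 1020 to 9380, 11900 to 27000 and 38200 to 55200 CPM. A further split that kept the P30 libraries together and mixed P4 with P10 gave 1 gene. Its mixed sets overlapped in Ttn, with 8220 to 27000 and 1020 to 11900 CPM. A split ordered by Ttn thus gave more genes than the split by age. Muscle RNA as the source of the 31 was not tested. Of the rest, 92 gave 0 and 6 gave 1 to 7 genes. Among those 6, the 3 with 6, 6 and 5 genes held P4 library 3, P4 library 4 and P30 library 3, the libraries with the fewest detected genes, in 1 set. For pairs of ages 10 splits of 6 libraries are too few for a share under 0.05. Splits with as many genes numbered 10 for P10 versus P4 (real 0, highest other 0), 1 for P30 versus P10 (3 and 0) and 1 for P30 versus P4 (14 and 4). Splits with as many lists past camera numbered 3 for P10 versus P4 (real 12, highest other 18), 2 for P30 versus P10 (22 and 22) and 1 for P30 versus P4 (13 and 12).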
